A study of Mus musculus with 24 samples.

How the data were processed

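Gene expression was measured by poly-A-selected RNA sequencing (Illumina TruSeq libraries, per the labels' protocols) of hearts from 24 male C57Bl/6 wild-type mice aged 12 weeks and kept under 12 h of light and 12 h of darkness. The labels define 4 groups of 6 mice: sedentary mice at ZT0 (ZT0-SED), exercised mice at ZT0 (ZT0-EX), sedentary mice at ZT12 (ZT12-SED) and exercised mice at ZT12 (ZT12-EX), where ZT0 is the start of the rest phase and ZT12 the start of the active phase. Zeitgeber time (ZT) counts hours from lights on. Exercised mice ran a single treadmill bout of 60 min at 10 m/min and 0% grade. The interval between the bout and tissue collection is not given in the sources used here. In every group, replicates 1, 2 and 3 were sequenced on flow cell 1 and replicates 4, 5 and 6 on flow cell 2, per the labels. Each label names a separate biological replicate.

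The deposited values are whole-number read counts per Ensembl gene, with 52350 genes in each library and no normalization. Reads were trimmed with Trimmomatic 0.39, aligned with HISAT2 2.2.1 to the GRCm39 build and counted with featureCounts 2.0.1, per the submitters' processing notes. The settings of these tools, the annotation release and the use of strand are not given in the sources used here, so antisense and overlapping genes were treated as uncertain. Symbols came from an annotation of the GRCm38 build matched by Ensembl identifier, and 257 identifiers without a symbol held 0.0013% of all counts. Coordinates of that build were not used here. The gene listed there as Arntl is called Bmal1. How featureCounts treated reads that align to more than one gene is also not given, and the near-identical pair Hspa1a and Hspa1b can exchange reads, so their separate values are uncertain.

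Library totals ranged from 9697334 to 23067191 counts. A count of 3 corresponded to 0.575 CPM (the unit for counts relative to a library total, here scaled by TMM) in the shallowest library, ZT12-SED 1, which sets how low a level could be seen there. No pair of libraries within a group looked like a repeated deposit, since the lowest chi-square per degree of freedom among 60 pairs was 14.6.

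Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups (15294 genes), scaled by TMM and fitted with robust quasi-likelihood models (estimateDisp, glmQLFit) to all 24 libraries at once, with group and flow cell as terms and 19 residual degrees of freedom. This main fit of all groups shares a single estimate of the spread. The median residual SD of log2 CPM was larger in ZT12 libraries (0.474) than in ZT0 libraries (0.295). A shared estimate can therefore make tests at ZT12 too lenient and tests at ZT0 too strict. Each adjusted p comes from edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested, unless another test is named, and 0.05 was the threshold. The comparisons were exercised against sedentary mice at ZT0 and at ZT12, the difference between those effects (interaction), and ZT12 against ZT0 in sedentary and in exercised mice. The exercise comparisons at ZT0 and ZT12 share no library, and neither do both time-of-day comparisons. Fold changes are on the log2 scale with their standard errors (SE), and n is 6 mice per group throughout. Values within a flow cell rest on 3 mice per group. Fold changes and list medians for a single flow cell are differences of mean log2 CPM (prior count 2), not model estimates. Both can therefore be smaller than the estimate from all mice. Adjusted p and gene counts for a flow cell, and folds in the section on processing, come from fits to that flow cell alone.

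Before the data were examined, 36 gene lists were fixed, 15 of them markers of cell types or neighbouring tissues. List shifts were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the data and the rotation test fry were run beside it. For each list, the number of members past the threshold is given over all genes and adjusted over the list alone. Genes were named by a rule fixed at the same time: up to 8 rises and 8 falls with the largest log2 fold change among genes past the threshold, with an average log2 CPM of at least 1 and the same sign on both flow cells, up to 4 members per list with the smallest p, and a preselected set (Per1, Per2, Bmal1, Nr1d1, Dbp, Fos, Egr1, Nr4a1, Nr4a3, Hspa1a, Hspa1b, Fkbp5, Pdk4, Ppargc1a, Nppa, Nppb and Vegfa). Predicted gene models were skipped. Genes outside this rule are marked as chosen after their values were seen. Some genes that the rule names are not reported here.

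Alternatives chosen before the data were examined were DESeq2 size factors, library totals without TMM, no filter and a stricter filter on low counts (at least 1 CPM in at least 6 libraries), DESeq2 1.42.0, limma-voom, no flow cell term, each flow cell alone, the compared groups alone, the replicate number as a block, removal of mitochondrially encoded genes, 2 surrogate variables (sva 3.50.0) and each library left out in turn. After the data were seen, 4 more were added: leaving out 3 libraries that stood apart, leaving out 6 libraries with skeletal muscle transcripts, offsets for GC content (per library, a natural spline with 5 degrees of freedom of log2 CPM on transcript GC content, available for 99.96% of tested genes), and those offsets with the replicate block. Each count was set beside 100 random regroupings of the libraries, drawn within flow cells with a fixed seed. For exercise effects and their difference, exercise labels were exchanged within each time. For time of day, and for the larger count at ZT0 than at ZT12, time labels were exchanged within sedentary and within exercised mice. For single lists, the number of regroupings that gave camera an equally small p was added after the data were seen.

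The scripts were tested on simulated counts with the real means and depths. For exercise at ZT0, the fit over 15174 genes recovered 56% of genes changed 2-fold and 92% of genes changed 4-fold, with 9 false calls. For the interaction, over the same 15174 genes, it recovered 17% and 75%, with 6 false calls, and for time of day in exercised mice 59% and 93%, with 9 false calls. Camera found the list raised in the simulation and called 0 of 35 unchanged lists over 15294 genes. The simulated genes varied independently, unlike members of real lists, so this does not give camera's rate of false calls here. In the other regroupings of the real libraries camera called a median of 9 lists for exercise at ZT0 and 7 at ZT12. GC offsets left 142 of 200 simulated changes called over 15166 genes, against 135 without them, in the simulation of exercise at ZT0.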

Results

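Transcript levels were measured in the hearts of 24 mice, 6 in each of 4 groups, to compare what a single treadmill bout did to cardiac transcription at the start of the rest phase (ZT0) and at the start of the active phase (ZT12). Library totals were 13822708 to 23067191 counts in ZT0-SED, 16487563 to 19948098 in ZT0-EX, 9697334 to 20424649 in ZT12-SED and 10810284 to 20974196 in ZT12-EX. Transcripts encoded by the mitochondrial genome took 36.7% ± 9.01 (SD, n = 12) of counts on flow cell 1 and 16.3% ± 6.20 (SD, n = 12) on flow cell 2. Their share was highest in the ZT12-SED libraries of flow cell 1, at 49.7% ± 7.87 (SD, n = 3), against 34.9% ± 2.19 in ZT12-EX, 30.7% ± 4.59 in ZT0-SED and 31.4% ± 1.68 in ZT0-EX there. On the same flow cell, gene levels relative to the average library fell with transcript GC content in ZT12-SED (mean Spearman correlation across genes -0.84) and ZT12-EX (-0.69), and less so in ZT0-SED (-0.23) and ZT0-EX (-0.23). The 12 libraries of flow cell 2 all had positive correlations, from 0.49 to 0.78, and genes are not independent replicates in any of these values. Transcripts of fast skeletal muscle such as Myh4 and Actn3, which mark that tissue and not heart muscle, were abundant in 6 libraries of flow cell 2, with a mean log2 CPM over 12 markers of 5.38 to 7.31 against 0.77 or less in every other library. These were all 3 ZT0-EX libraries of that flow cell and replicate 6 of each other group. The first principal component held 59.1% of the variance. The 3 libraries least correlated with the rest were ZT12-SED 1, ZT12-SED 2 and ZT12-EX 4.

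**Figure D1:**
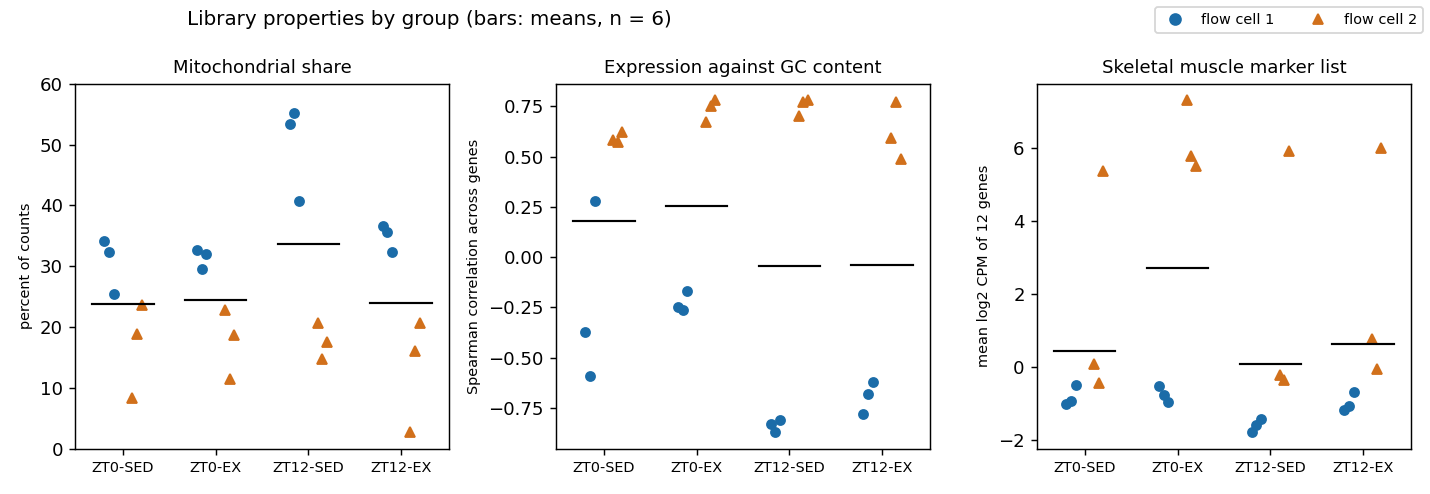
Share of counts from mitochondrially encoded transcripts (%), Spearman correlation of gene levels with transcript GC content, and mean log2 CPM of 12 skeletal muscle markers, for each of the 24 libraries by group, with bars at the means. Circles are flow cell 1 and triangles flow cell 2, and 6 libraries of flow cell 2 sit at 5.38 or more on the skeletal muscle axis.

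Exercise at ZT0 raised heat shock genes, immediate early genes, glucocorticoid-responsive genes and Per1 and Per2 of the circadian clock, and lowered the chemokine receptors Ccr2 and Cx3cr1. The inducible HSP70 genes rose most, Hspa1b (ENSMUSG00000090877) by 4.70 ± 0.65 on the log2 scale (SE, n = 6 per group, adjusted p = 0.000146) and Hspa1a (ENSMUSG00000091971) by 4.59 ± 0.54 (adjusted p = 2.11e-05). Hspa1a averaged 1.90 ± 1.23 CPM (SD, n = 6) in sedentary mice and 51.0 ± 45.7 CPM in exercised mice, with each exercised library above each sedentary one. Of 23 measured cytosolic chaperones, 7 rose, 0 fell and 16 did not pass, and 12 rose when adjusted over the list alone. They included the co-chaperones Hsph1 (1.97 ± 0.27) and Dnajb1 (1.30 ± 0.19). Of 29 immediate early genes, which respond to stimuli without new protein synthesis, 12 rose, 0 fell and 17 did not pass, and 17 rose when adjusted over the list alone. Nr4a3 (ENSMUSG00000028341, 3.24 ± 0.31) and Nr4a1 (ENSMUSG00000023034, 2.88 ± 0.39), which encode orphan nuclear receptors, rose most among them, followed by Atf3 (2.25 ± 0.33) and Fos (1.74 ± 0.39). Of 19 glucocorticoid-responsive genes, 13 rose, 0 fell and 6 did not pass, and 16 rose when adjusted over the list alone. Among them were the cell cycle inhibitor Cdkn1a (ENSMUSG00000023067, 2.00 ± 0.19), Ddit4, an inhibitor of mTORC1 (2.07 ± 0.29), and Fkbp5 (ENSMUSG00000024222, 1.39 ± 0.23), a co-chaperone of the glucocorticoid receptor. Per1 belongs to that list and to the clock list, where it (ENSMUSG00000020893, 3.08 ± 0.39), Per2 (ENSMUSG00000055866, 1.72 ± 0.23) and the repressor Bhlhe40 (0.93 ± 0.23) rose and the other 16 of 19 members did not pass. Adjusted over the list alone, 4 clock genes rose. Further large rises were in Irs2, an adaptor of insulin signalling (2.99 ± 0.39), the salt-inducible kinase Sik1 (2.70 ± 0.28) and Fam107a (2.60 ± 0.26). The potassium channel gene Kcna5 rose by 1.55 ± 0.25 and was the 1 of 25 ion channel and calcium handling genes to pass. Hif3a rose by 2.07 ± 0.39 and Chac1, a glutathione-degrading enzyme of the integrated stress response, by 2.01 ± 0.40. The atrogene Fbxo32, a ubiquitin ligase of muscle, rose by 1.16 ± 0.28, with 0.72 on flow cell 1 and 1.63 on flow cell 2, and did not pass on either flow cell alone.

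Among genes that fell at ZT0, Cx3cr1 changed by -2.06 ± 0.33 and Ccr2 (ENSMUSG00000049103) by -1.79 ± 0.24 (adjusted p = 0.000766 and 0.00012). Ccr2, the receptor of monocyte recruitment, averaged 7.09 ± 2.19 CPM (SD, n = 6) in sedentary and 2.17 ± 0.91 CPM in exercised mice. Of 12 macrophage and monocyte markers, Ccr2 and Cx3cr1 fell, 0 rose and 10 did not pass, and 3 fell when adjusted over the list alone. The chemokine gene Ccl7 (-1.37 ± 0.29), the cytokine signalling inhibitor Socs1 (-1.38 ± 0.32), the apelin receptor Aplnr (-1.45 ± 0.26) and the fibroblast transcription factor Tcf21 (-0.94 ± 0.22) also fell. Of 8 lymphocyte markers, 0 passed over all genes by edgeR and 5 fell when adjusted over the list alone, with Ms4a1 at -1.43 ± 0.41 (adjusted p = 0.118) and Ighm at -0.91 ± 0.28 (adjusted p = 0.179). Genes of fuel use and vessel growth that are often followed after exercise did not pass, with Pdk4 at 1.05 ± 0.31 (adjusted p = 0.139, past the threshold with DESeq2, surrogate variables, GC offsets, the compared groups alone or without the libraries that stood apart), Ppargc1a at 0.86 ± 0.29 (adjusted p = 0.242) and Vegfa at 0.76 ± 0.29 (adjusted p = 0.342). In all, 165 of 15294 genes passed, 121 higher and 44 lower, and 104 of them differed more than 2-fold. Camera called 14 of 36 lists, of which the glucocorticoid-responsive (median log2 fold 1.23, adjusted p = 4.07e-41), immediate early (0.75, adjusted p = 1.02e-23) and heat shock (0.58, adjusted p = 3.01e-17) lists were also called with an estimated correlation (adjusted p = 1.9e-05, 0.0028 and 0.000124). The clock list was called higher (median 0.27, adjusted p = 1.06e-05, adjusted p = 0.127 with an estimated correlation). The lymphocyte list (-0.99, adjusted p = 2.45e-05) and the macrophage list (-0.31, adjusted p = 2.78e-05) were called lower, with adjusted p = 0.169 and 0.194 with an estimated correlation. The macrophage median was 0.04 on flow cell 1, where the list was not called (adjusted p = 0.305), and -0.65 on flow cell 2. The skeletal muscle list had a median of 1.88 (adjusted p = 0.000172, and 0.449 with an estimated correlation), and on flow cell 1, which held no library with those transcripts, it was not called (adjusted p = 0.554). On flow cell 1 alone 39 genes passed and on flow cell 2 alone 13. Without the 6 libraries with skeletal muscle transcripts 51 passed, and the macrophage list was not called (adjusted p = 0.259). Fbxo32, Hsph1, Fos, Bhlhe40, Chac1, Kcna5, Cx3cr1, Aplnr, Ccl7, Socs1 and Tcf21 did not pass there. That fit keeps 3 ZT0-EX libraries, all on flow cell 1. Muscle RNA, fewer mice and flow cell cannot be told apart as the reason. On flow cells 1 and 2, Hspa1a rose by 3.74 and 4.85, Per1 by 3.22 and 2.83, and Ccr2 changed by -1.48 and -1.92.

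**Figure D2:**
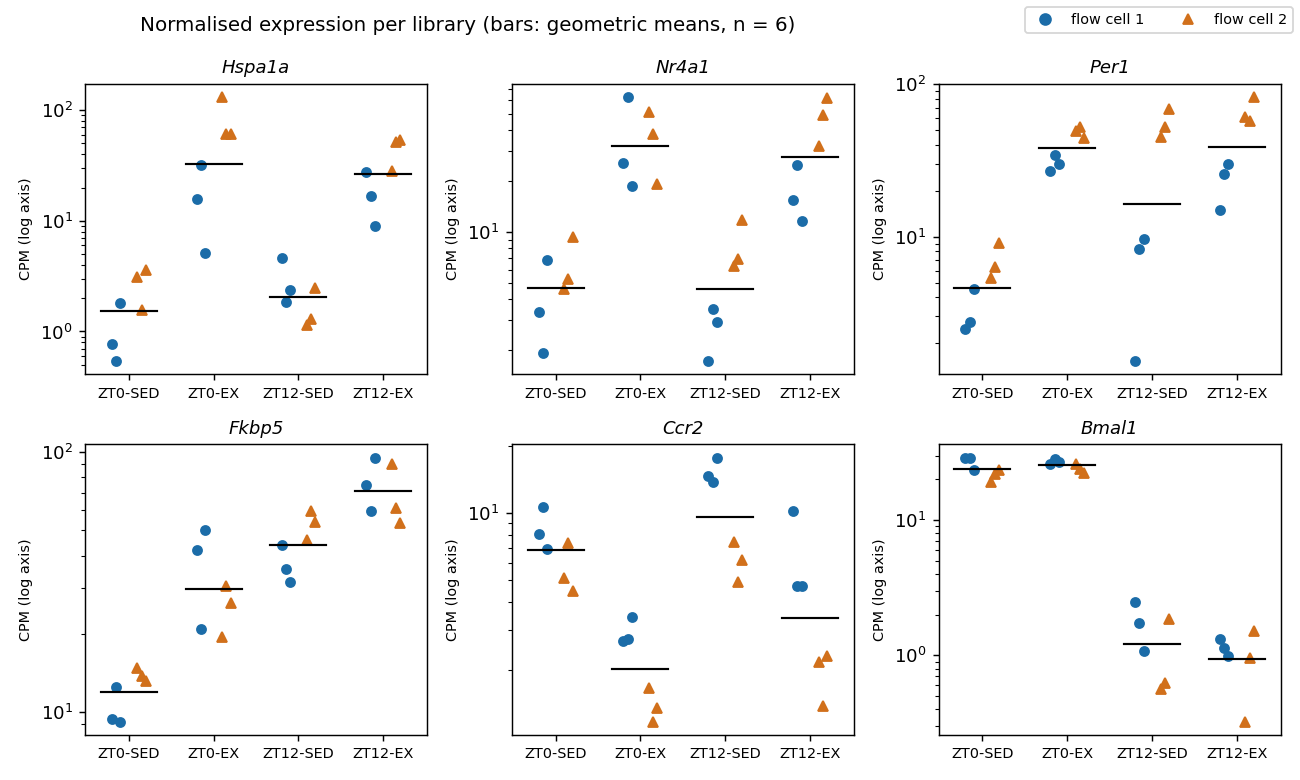
CPM (log axis) of Hspa1a, Nr4a1, Per1, Fkbp5, Ccr2 and Bmal1 in each of the 24 libraries by group, with circles for flow cell 1, triangles for flow cell 2 and bars at the geometric means. Hspa1a averaged 1.90 CPM in ZT0-SED and 51.0 CPM in ZT0-EX, and Bmal1 averaged 24.3 CPM in ZT0-SED and 1.40 CPM in ZT12-SED.

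At ZT12, the active phase, exercise again raised 9 of 23 heat shock genes and 4 of 29 immediate early genes and lowered Ccr2. Hspa1a rose by 3.61 ± 0.54 (SE, n = 6 per group, adjusted p = 0.00191) and Hspa1b by 3.49 ± 0.64 (adjusted p = 0.0113). Of the 23 chaperones, 9 rose, 0 fell and 14 did not pass, and 11 rose when adjusted over the list alone. They included Hsph1 (1.73 ± 0.27), the small heat shock protein Hspb1 (1.43 ± 0.31), Dnajb1 (1.35 ± 0.19) and Stip1 (0.89 ± 0.15), which links HSP70 to HSP90. Of the 29 immediate early genes, Nr4a1 (2.53 ± 0.39), Nr4a3 (2.35 ± 0.31), Atf3 (1.98 ± 0.34) and Maff (0.99 ± 0.20) rose and 25 did not pass. Adjusted over the list alone, 10 rose and 1 fell. Of the 19 glucocorticoid-responsive genes, Cdkn1a (1.16 ± 0.19) rose and 18 did not pass, and 5 rose when adjusted over the list alone. No clock gene passed in the main edgeR fit (0 of 19 over all genes, 1 rose when adjusted over the list alone), with Per1 at 0.84 ± 0.36 (adjusted p = 0.273) and Per2 at 0.51 ± 0.22 (adjusted p = 0.275). Per1 stood at 2.15 on flow cell 1 and 0.29 on flow cell 2. With 2 surrogate variables 2 clock genes rose. Camera called the clock list higher without the 3 libraries that stood apart (adjusted p = 0.0331), but not in all mice (0.416) or with surrogate variables (0.157). Falls were seen in the lysophospholipid receptor gene Gpr34 (-1.72 ± 0.28), Ccr2 (-1.39 ± 0.24) and Aplnr (-1.25 ± 0.27), and in Adrb1, the main beta-adrenergic receptor of cardiomyocytes (-1.11 ± 0.25, adjusted p = 0.0492). Ccr2 averaged 10.7 ± 5.23 CPM (SD, n = 6) in sedentary and 4.25 ± 3.23 CPM in exercised mice. Cx3cr1 stood at -0.96 ± 0.36 (adjusted p = 0.244). The mitochondrially encoded mt-Co3 fell by 1.62 ± 0.34 (adjusted p = 0.0321), the other 12 mitochondrially encoded transcripts did not pass over all genes, and 9 of 13 fell when adjusted over the list alone, beside the higher mitochondrial share of the ZT12-SED libraries of flow cell 1 given above. In total 45 genes passed, 29 higher and 16 lower. Camera called 8 of 36 lists, and the heat shock list (median 0.47, adjusted p = 2.58e-13) was called with an estimated correlation too (adjusted p = 0.00082). The mitochondrially encoded list (median -1.04, adjusted p = 5.83e-09, adjusted p = 0.261 with an estimated correlation) was called lower. Its medians were -1.27 on flow cell 1 and -0.97 on flow cell 2, and camera called it on each alone (adjusted p = 4.79e-11 and 0.000153). On flow cell 2 the mitochondrial share was 14.7 to 20.7% in ZT12-SED and 2.7 to 20.6% in ZT12-EX. The immediate early (0.43, adjusted p = 1.2e-08) and glucocorticoid-responsive lists (0.53, adjusted p = 3.79e-05) were called higher, each with adjusted p = 0.236 with an estimated correlation. Across genes, the exercise effect at ZT12 correlated with transcript GC content at 0.749 on flow cell 1 and 0.463 on flow cell 2 (Spearman). With GC offsets the median was 0.21 for the immediate early (adjusted p = 9.04e-05), 0.30 for the glucocorticoid-responsive (adjusted p = 0.00122), -0.56 for the mitochondrially encoded (adjusted p = 1.95e-05) and 0.44 for the heat shock list (adjusted p = 1.6e-19), and Hspa1b, Maff, Adrb1 and mt-Co3 no longer passed. The medians on flow cells 1 and 2 were 0.59 and 0.28 for the immediate early, 0.62 and 0.21 for the glucocorticoid-responsive and 0.61 and 0.48 for the heat shock list. The adipocyte list (median 0.95, adjusted p = 0.000164, and 0.261 with an estimated correlation) was called higher with 0 of 8 members past the threshold and 2 when adjusted over the list alone, at medians of 2.14 on flow cell 1 and 0.56 on flow cell 2. On flow cell 1 alone 20 genes passed and on flow cell 2 alone 4. A fit to the ZT12 groups alone, with its own estimate of the spread, gave 14, all among the 45.

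**Figure D3:**
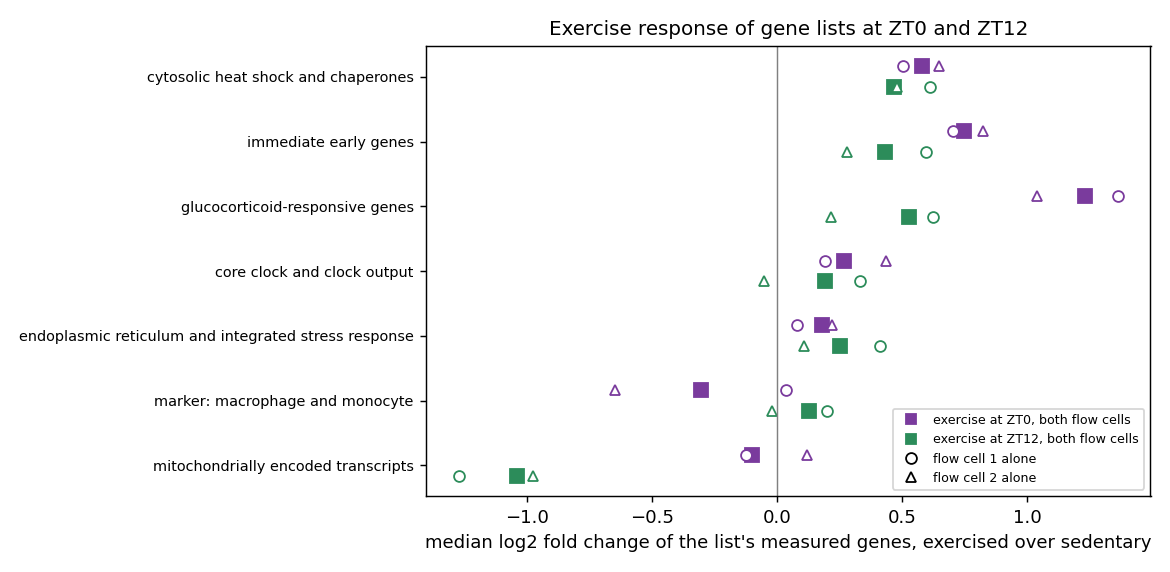
Median log2 fold change after exercise of 7 gene lists at ZT0 (purple) and ZT12 (green), with squares for all mice and open circles and triangles for flow cells 1 and 2. The glucocorticoid-responsive list had a median of 1.23 at ZT0 and 0.53 at ZT12.

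The genes changed by exercise at both times were 27 in number, 18 higher and 9 lower, against 0.229 and 0.046 expected if the lists were independent, and 0 changed in opposite directions. The 18 rises held 7 chaperone genes, among them Hspa1a, Hspa1b, Hsph1 and Dnajb1, with Nr4a1, Nr4a3, Atf3, Maff, Sik1 and Cdkn1a. The falls included Ccr2, Gpr34, Aplnr, Skida1 and Evi2a. The Toll-like receptor relative Cd180 (-1.21 ± 0.27 at ZT0 and -1.32 ± 0.27 at ZT12) and the oxysterol receptor Gpr183 (-1.89 ± 0.24 and -1.80 ± 0.26), both chosen after their values were seen, fell as well. Of the 165 genes that passed at ZT0, 153 had the same sign at ZT12, and all 45 that passed at ZT12 had the same sign at ZT0. The test of the difference between both exercise effects gave 0 genes with edgeR (smallest adjusted p = 0.125), with 1226 at an unadjusted p below 0.05, 0 with limma-voom and 5 with DESeq2. Per1 stood at -2.24 ± 0.51 (ZT12 effect minus ZT0 effect, adjusted p = 0.506), Kcna5 at -1.51 ± 0.35 (adjusted p = 0.542) and Per2 at -1.21 ± 0.32 (adjusted p = 0.571). In single genes a smaller rise at ZT12 was thus not shown by the main edgeR fit. In edgeR with offsets for GC content, Per1 (-2.40, adjusted p = 0.00234) and Fam107a (-2.04, adjusted p = 0.0399) passed. In edgeR with 2 surrogate variables Per1 passed (-2.25, adjusted p = 7.52e-06) and Fam107a did not. Camera called 10 of 36 lists for the difference, and 1 of them, the glucocorticoid-responsive genes, with an estimated correlation too (median -0.77, adjusted p = 1.98e-11, and 0.0342 with an estimated correlation). Of its 19 members 0 passed over all genes by edgeR and 9 were lower when adjusted over the list alone, such as Klf9 (-1.25 ± 0.34), Klf15 (-1.08 ± 0.29) and Cebpd (-1.45 ± 0.40). Its median was -0.63 on flow cell 1 and -0.80 on flow cell 2. Camera did not call the heat shock list for the difference (median 0.05, adjusted p = 0.725), with Hspa1a at -0.98 ± 0.71 (adjusted p = 0.599).

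Between ZT12 and ZT0 in sedentary mice clock genes differed strongly, with Bmal1 (also known as Arntl) and Npas2, the activating arm of the clock, lower at ZT12 and the Per genes and Dbp higher. Bmal1 (ENSMUSG00000055116) changed by -4.21 ± 0.26 (SE, n = 6 per group, adjusted p = 3.77e-10), from 24.3 ± 3.81 to 1.40 ± 0.77 CPM (SD, n = 6). Npas2 (ENSMUSG00000026077) changed by -3.12 ± 0.20, while Per2 rose by 3.42 ± 0.25, Per3 by 3.04 ± 0.21 and the output gene Dbp (ENSMUSG00000059824) by 2.48 ± 0.29. Of 19 clock genes 10 were higher, 3 lower and 6 did not pass, with 11 and 4 when adjusted over the list alone. Bmal1 changed by -3.91 on flow cell 1 and -4.43 on flow cell 2, and Per2 rose by 3.40 on both. Per1 was higher by 2.23 ± 0.38, with 0.65 on flow cell 1 and 2.99 on flow cell 2. Of 19 glucocorticoid-responsive genes 11 were higher, 1 lower and 7 did not pass, with 15 and 1 when adjusted over the list alone. Zbtb16 (2.49 ± 0.43), Fkbp5 (1.89 ± 0.24), Tsc22d3 (1.88 ± 0.30) and Klf9 (1.55 ± 0.24) were among them. Genes outside these lists that were far higher at ZT12 included Fam107a (3.10 ± 0.27), Hif3a (2.70 ± 0.39) and Mthfd1l, an enzyme of mitochondrial folate metabolism (2.61 ± 0.26). Spon2 (ENSMUSG00000037379), which encodes a secreted matrix protein, changed by -3.57 ± 0.47 and the tight junction gene Cldn5 by -2.35 ± 0.43. Of 20 collagen and matrix genes 10 were lower, 0 higher and 10 did not pass, with 12 lower when adjusted over the list alone, such as Eln (-1.44 ± 0.21), Col15a1 (-1.28 ± 0.22) and Col4a1 (-1.14 ± 0.26). Of 18 cardiac stress genes 4 were lower and 14 did not pass, with 7 lower when adjusted over the list alone. They were the natriuretic peptide gene Nppb (-1.92 ± 0.35), Cited4 (-2.05 ± 0.37), Tnfrsf12a (-1.53 ± 0.26) and the calcineurin target Rcan1 (-1.11 ± 0.14). Of 18 sterol synthesis and uptake genes 3 were lower, 0 higher and 15 did not pass, with 7 lower when adjusted over the list alone, and Sqle, an enzyme of cholesterol synthesis, was among them (-1.34 ± 0.38).

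In all, 795 genes differed by time of day in sedentary mice, 376 higher and 419 lower at ZT12. Camera called 6 of 36 lists, with the glucocorticoid-responsive list (median 0.97, adjusted p = 2.68e-11) called also with an estimated correlation (adjusted p = 0.038). The clock list (0.94, adjusted p = 5.47e-07) was called higher, and the matrix (-0.76, adjusted p = 4.06e-07), cardiac stress (-0.66, adjusted p = 0.000325) and sterol lists (-0.31, adjusted p = 0.041) lower, with adjusted p = 0.105, 0.333, 0.143 and 0.211 in that order with an estimated correlation. The mitochondrially encoded list (0.69, adjusted p = 0.00948, and 0.786 with an estimated correlation) was called higher beside the mitochondrial share of 49.7% in the ZT12-SED libraries of flow cell 1, with mt-Co3 alone past the threshold over all genes (1.37 ± 0.33) and 2 members when adjusted over the list alone. With GC offsets it was not called (adjusted p = 0.473), while the matrix list was called at a smaller median (-0.38, adjusted p = 0.000175) with 2 members lower, Col4a1 not among them. The cardiac stress list was called with GC offsets at a median of -0.30 (adjusted p = 0.000981), and its median was -0.91 on flow cell 1 and -0.04 on flow cell 2. Camera called it lower on each flow cell alone (adjusted p = 0.00198 and 0.00143). The matrix medians were -1.28 and -0.41 on flow cells 1 and 2, where the matrix list was called lower too (adjusted p = 4.06e-05 and 1.6e-08). The sterol list was not called on flow cell 1 (adjusted p = 0.103). The glucocorticoid-responsive list had a larger median with GC offsets, 1.46 (adjusted p = 9.6e-29), and medians of 0.66 and 1.16 on flow cells 1 and 2. On flow cell 1 alone, where the GC trend was stronger in both ZT12 groups than in the ZT0 groups, 6552 genes passed, and on flow cell 2 alone 35, of which 33 were among the 795.

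**Figure D4:**
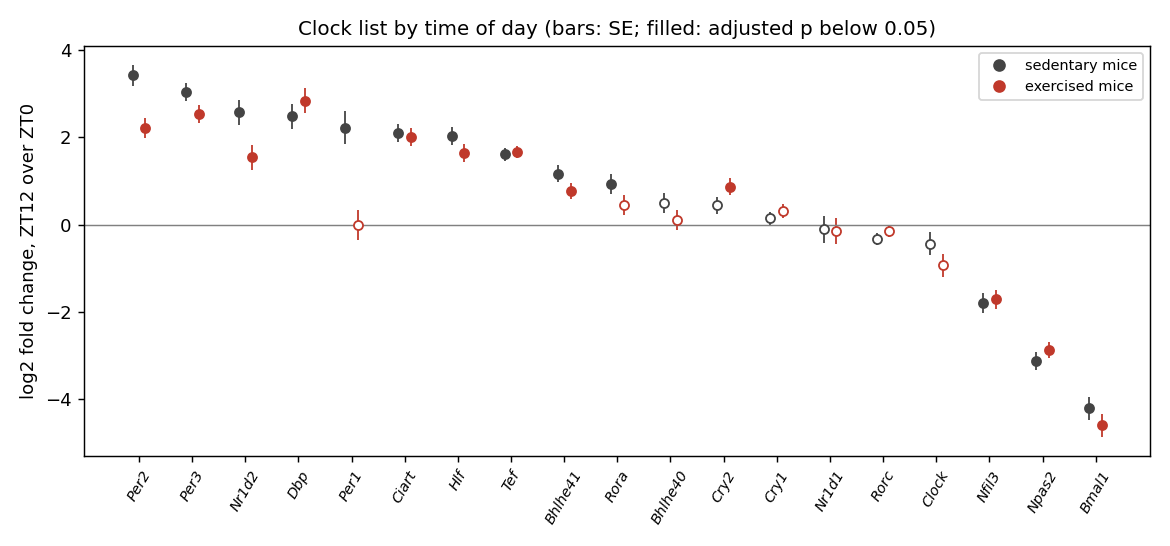
Log2 fold change, ZT12 over ZT0, of 19 clock genes in sedentary and in exercised mice, with bars for the standard error and filled symbols for adjusted p below 0.05. Bmal1 lies at -4.21 in sedentary and -4.60 in exercised mice, and Per1 at 2.23 and -0.01.

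In exercised mice Bmal1 and Npas2 were again lower at ZT12 than at ZT0 and Dbp, Per2 and Per3 higher, while Per1 did not pass the test. Bmal1 changed by -4.60 ± 0.27 (SE, n = 6 per group, adjusted p = 5.98e-11) and Npas2 by -2.87 ± 0.19, while Dbp rose by 2.85 ± 0.29, Per3 by 2.53 ± 0.20, Per2 by 2.21 ± 0.23 and Ciart by 2.01 ± 0.20. Per1 stood at -0.01 ± 0.35 (adjusted p = 0.993), at 39.6 ± 10.5 CPM (SD, n = 6) in ZT0-EX and 45.4 ± 25.9 CPM in ZT12-EX. With 2 surrogate variables the value for Per1, time of day in exercised mice, was 0.56 and passed (adjusted p = 0.0203). Of 19 clock genes 9 were higher, 3 lower and 7 did not pass, with 9 and 4 when adjusted over the list alone. Of 20 matrix genes 8 were lower, 0 higher and 12 did not pass, with 11 lower and 1 higher when adjusted over the list alone. Col4a1 (-1.51 ± 0.26), Fbn1 (-1.36 ± 0.24), Col15a1 (-1.34 ± 0.22) and Col1a1 (-1.27 ± 0.23) were among them. The cardiac stress genes Nppb (-1.62 ± 0.35), Rcan1 (-1.31 ± 0.14) and Tnfrsf12a (-1.05 ± 0.26) were lower, 15 of 18 did not pass, and 5 were lower when adjusted over the list alone. Of 19 glucocorticoid-responsive genes Zbtb16 (1.79 ± 0.42), Fkbp5 (1.19 ± 0.23) and 1 more were higher and Cdkn1a (-1.56 ± 0.18) lower, and the list was not called (median 0.20, adjusted p = 0.187) except with GC offsets (adjusted p = 0.0262) and on flow cell 2 (adjusted p = 0.0347). The alarmin Il33 (1.87 ± 0.30), the glutathione transferase Gsta3 (1.81 ± 0.26) and the detoxifying enzymes Aldh3a1 (2.02 ± 0.38) and Cyp2e1 (2.32 ± 0.55) were higher at ZT12. Altogether 252 genes passed, 124 higher and 128 lower. Of these, 157 also passed in sedentary mice, 60 higher and 97 lower in both, against 3.05 and 3.51 expected if independent. On flow cell 1 both differences followed GC content (Spearman -0.833 in sedentary and -0.731 in exercised mice). A shared trend can raise the overlap, so independence is a weak baseline for it. Spon2, Slc41a3, Col5a3 and Tmem171 were lower and Mthfd1l higher in both conditions. Camera called 14 of 36 lists, and 0 with an estimated correlation, where 7 had an unadjusted p below 0.05 and fry called 12. The matrix (median -0.76, adjusted p = 4.68e-09, and 0.183 with an estimated correlation) and cardiac stress lists (-0.69, adjusted p = 8.88e-07, and 0.0676) were lower and the clock list higher (0.45, adjusted p = 0.000109, and 0.183). Across genes, this time-of-day difference correlated with transcript GC content at -0.731 on flow cell 1 and 0.231 on flow cell 2 (Spearman). With GC offsets the matrix median was -0.41 (adjusted p = 8.47e-07, 7 members lower), against -1.10 and -0.43 on flow cells 1 and 2 without them. The skeletal muscle list (-1.37, adjusted p = 0.00159, and 0.505 with an estimated correlation) was lower, where 3 ZT0-EX libraries and 1 ZT12-EX library held those transcripts, and it was not called on flow cell 1 (adjusted p = 0.852). On flow cell 2 alone 17 genes passed, and 86 did without the libraries with skeletal muscle transcripts, a fit that keeps 3 ZT0-EX libraries, all on flow cell 1.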

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

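The tests of GC content, skeletal muscle RNA, marker genes, spread among libraries, baseline level and single-list regroupings were chosen after the results they address were seen, while the regroupings behind counts of genes and lists were planned.

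Among 496 sets of 6 libraries examined, 23 held a library separated from the others by an unusually large gap, and 24.8 would be by chance, since about 1 in 20 sets is. No measure of library quality gave such a gap in 12 sets, lists gave 7 in 144 sets (7.2 by chance) and genes 16 in 340 (17 by chance). The values that follow are the gap as a share of the group's range. The skeletal muscle list was far higher in replicate 6 of ZT0-SED (0.831), ZT12-SED (0.798) and ZT12-EX (0.73). In ZT12-EX 4 the hypoxia list (0.817) and the clock genes Bhlhe40 (0.807) and Bmal1 (0.682) and the immediate early gene Nr4a3 (0.74) were low and the oxidative phosphorylation list (0.676) high. In ZT12-SED 1 Hif3a (0.873), Bhlhe40 (0.712) and Aplnr (0.657) were low, and Adrb1 (0.725) and Tsc22d3 (0.716) high. In ZT12-SED 3 Irs2 (0.712) was low and Fbn1 (0.65) high. Among ZT0-SED libraries, Atf3 was high in replicate 4 (0.678), Avil (0.672) in replicate 6, and Herpud1 (0.67) and Ighm (0.744) in replicate 3. The atrial cardiomyocyte list was low in ZT12-EX 2 (0.744), branched-chain amino acid genes were low in ZT0-EX 1 (0.667), Pdk4 was high in ZT0-EX 3 (0.752) and Skida1 low in ZT0-EX 5 (0.858).

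By camera, 10 lists responded differently to exercise at ZT12 and at ZT0. Medians of the difference, ZT12 minus ZT0, were -0.766 for glucocorticoid-responsive genes, -0.868 for mitochondrially encoded transcripts, -0.385 for clock genes, -0.348 for ion channels and calcium handling and -0.225 for immediate early genes. They were 1.22 for atrial cardiomyocyte markers, 0.711 for epicardium, 0.645 for adipocyte markers, 0.45 for macrophage markers and 0.372 for cell cycle genes. With an estimated correlation only the glucocorticoid-responsive list was called (adjusted p = 0.0342), and the other 9 had adjusted p of 0.546 or more. As many lists or more were called in 41 of 100 regroupings (real 10, highest other 17). These exchange exercise labels within each time, so a real exercise effect can turn into a false difference between times. They cannot decide whether the number of lists arose by chance, and chance cannot be excluded for it. For the glucocorticoid-responsive list alone, 8 of 100 regroupings gave camera a p as small as the real 5.49e-13 (smallest other 1.13e-30), with the same limit.

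Chance is unlikely for the counts of genes changed by exercise at ZT0, where 1 of 100 regroupings, the real one, gave as many (165, highest other 84), and at ZT12 (1 of 100, 45, highest other 12). It is also unlikely for the 27 genes changed at both times (1 of 100, highest other 0), and for time of day in sedentary (1 of 100, 795, highest other 262) and exercised mice (1 of 100, 252, highest other 0). A share of 1 of 100 is the lowest that 100 regroupings can give. It was not adjusted for the number of counts tested and does not exclude chance. Chance stays open for the genes with an unadjusted p below 0.05 in the test of the difference between times, where 12 of 100 gave as many (1226, highest other 3889). These regroupings do not hold the exercise effects equal at both times, so they cannot measure chance for the difference. What gave 3889 genes in that regrouping was not tested. The larger count at ZT0 than at ZT12 by 120 genes was matched in 10 of 100 regroupings of time labels (highest other 1374). Those regroupings mix libraries that differ by time of day, so they cannot decide whether the exercise effects were equal. A weaker response at ZT12 is not shown by these counts. As many lists were called in 16 of 100 regroupings for exercise at ZT0 (14, highest other 19) and 43 of 100 at ZT12 (8, highest other 17), and for time of day in 58 of 100 in sedentary (6, highest other 14) and 6 of 100 in exercised mice (14, highest other 18).

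The sedentary time-of-day difference falls into a clock part and a much larger remainder. The tables argue against a GC trend between libraries as the cause in the clock genes, since all 13 that passed were called in the same direction with GC offsets. For genes outside the clock and glucocorticoid-responsive lists, the fold correlated with GC content at -0.833 across genes on flow cell 1 and -0.0417 on flow cell 2, and 345 of 771 (44.7%) were still called with offsets. The matrix list went from a median of -0.76 (interquartile range 0.89) to -0.38 (0.42) with offsets. On flow cell 1 levels followed GC content at -0.84 in ZT12-SED and -0.69 in ZT12-EX, against -0.23 in each ZT0 group. RNA handling or library preparation of those ZT12 libraries is therefore a candidate source of many of these calls. However, a simulated GC trend in the ZT12-SED libraries of flow cell 1 gave 0 false sedentary time-of-day calls without offsets. That trend was not matched to the real one in strength and was not placed on ZT12-EX, so it cannot decide. A biological time-of-day difference in the same genes stays open, untested by other means.

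Glucocorticoid-responsive genes had a smaller exercise effect at ZT12 than at ZT0. The median difference was -0.766 in all mice, -0.63 on flow cell 1 and -0.80 on flow cell 2, and as this is the pattern itself, a larger spread among ZT12 libraries (residual SD 0.474 against 0.295) cannot be told apart from other causes. The tables argue against GC content, since the median was -0.82 with offsets. A ceiling in members already high at ZT12 cannot be told apart either. It would give a negative correlation across the 19 members between the sedentary time-of-day fold and the interaction fold. That correlation was -0.305 with flow cell 2 as baseline and flow cell 1 for the interaction, and 0.128 the other way round. The 8 of 100 regroupings with a camera p as small cannot decide on chance, since they can turn an exercise effect into a difference. Chance stays open too, beside a time-of-day difference in hormone response that was not tested.

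The receptor genes Ccr2, Cd180, Gpr183 and Gpr34, a set chosen after its values were seen, had median exercise changes of -1.54 at ZT0 and -1.56 at ZT12. Cd180 and Gpr183 rest on few reads, averaging 0.595 and 0.563 CPM in ZT0-EX and 0.784 and 0.465 CPM in ZT12-EX. In exercised libraries 3 counts corresponded to 0.13 to 0.324 CPM. A loss of macrophages and monocytes of every kind should lower their other 11 markers by about as much, and these had medians of -0.296 at ZT0 (0.0444 and -0.637 on flow cells 1 and 2, single markers from -2.06 to 0.317) and 0.146 at ZT12 (0.322 and 0.0245), although without the 3 libraries that stood apart the whole list, Ccr2 included, was called lower at ZT12 (adjusted p = 9.55e-05, against 0.601). Skeletal muscle transcripts were abundant in no library of flow cell 1, where the medians were -1.38 and -1.36, and with GC offsets they were -1.53 and -1.29. Lymphocyte markers, of cells that can carry some of these receptors too, had medians of -0.985 at ZT0 (-0.86 and -0.778 on flow cells 1 and 2) and -0.421 at ZT12 (0.0758 and -0.348), and that list was called lower at ZT0, and at ZT12 with 2 surrogate variables (adjusted p = 0.00373) or without the 3 libraries that stood apart (0.00217) but not in all mice (0.387). Fewer lymphocytes, a partial loss of macrophages or of a subset that carries the receptors, or lower transcription of the receptor genes after exercise may account for the fall, and none of these was tested.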

How the results depend on the processing

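Leaving out the 3 libraries that stood apart or the 6 with skeletal muscle transcripts, GC offsets, and those offsets with the replicate block were tests chosen after the data were seen. Counts of genes are given for exercise at ZT0 (165), exercise at ZT12 (45), both times (27), time of day in sedentary (795) and in exercised mice (252), and for the difference between exercise effects (0). Those not listed stayed within 1.5 times these counts or, for the difference, at 0. A similar count can hold other genes. With 2 surrogate variables 815 passed for sedentary time of day, 457 of them among the 795. At ZT12, 59 passed with GC offsets and 47 without the libraries that stood apart, with 32 and 26 among the 45. On flow cell 1 alone 8 of 20 were. With DESeq2 size factors 759 of 800 (sedentary) and 43 of 44 (ZT12) were shared.

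With library totals in place of TMM, 85 genes passed for exercise at ZT0, 25 at ZT12 (20 higher and 5 lower, against 29 and 16), 234 for time of day in sedentary mice (69 and 165, against 376 and 419) and 85 in exercised mice. DESeq2 called 267, 221, 66, 2845 and 535 in the order given, and 5 for the difference (Dcbld1, Stc1 and Tob2, chosen after their values were seen, with Fam107a and Per1). With no filter 478 passed for sedentary time of day and 1, Fam107a, for the difference. Without the flow cell term the counts were 51, 10, 9, 129 and 62. On flow cell 1 they were 39, 20, 7 and 6552 (sedentary), and on flow cell 2 they were 13, 4, 4, 35 and 17. Fits to the compared groups alone, each with its own estimate of the spread, gave 413, 14, 12 and 243 (sedentary). With 2 surrogate variables 510, 188, 111 and 1383 (exercised) passed, and 5 for the difference (Per1, with Tob2, Sema6b, Cebpb and Slc25a33, chosen after their values were seen). Without the libraries that stood apart 381 passed at ZT0, 437 and 1017 for time of day, and 1 (Per1) for the difference. Without those with skeletal muscle transcripts 51 passed at ZT0, 16 at both times, and 3133 and 86 for time of day. That fit keeps 3 ZT0-EX libraries, all on flow cell 1. GC offsets gave 515 for sedentary (310 higher and 205 lower, 367 of them among the 795) and 391 for exercised mice, and 2 (Per1 and Fam107a) for the difference. The cause was not tested.

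Leaving out 1 library at a time gave 91 to 231 genes for exercise at ZT0, 22 to 77 at ZT12, 18 to 40 at both times, 305 to 3273 and 135 to 455 for time of day, and 0 to 1 for the difference. For exercise at ZT0 the count fell most without ZT0-EX 2 (98), 3 (99), 4 (108) and 5 (91) and ZT0-SED 4 (108) and 5 (108). At ZT12 it was 25 without ZT12-SED 2, 26 without 3, 23 without 4 and 77 without 6, 27 without ZT12-EX 2, 22 without 3 and 69 without 4, and 29 without ZT0-EX 5. For genes changed, time of day in sedentary mice, it was 384 without ZT12-SED 1, 322 without 2 and 423 without 3, 329 without ZT0-SED 1, 381 without 2, 305 without 3, 447 without 4 and 2808 without 6, and 3273 without ZT12-EX 4. For exercised mice it was 135 without ZT12-EX 1, 150 without 3, 455 without 4 and 390 without 6, and 160 without ZT0-EX 2, 166 without 3 and 166 without 5. For the difference, Per1 passed without ZT12-SED 1, Fam107a without ZT12-SED 3 and Tob2 without ZT12-EX 6.

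The numbers of lists called by camera were 14 and 8 for exercise at ZT0 and ZT12, 10 for the difference, and 6 and 14 for time of day. An estimated correlation gave 3, 1, 1, 1 and 0. Fry, which tests something else, gave 9 for exercise at ZT0 and 1 for the difference. On flow cell 1 the counts were 8 (ZT0), 5 (difference) and 7 (exercised time of day), and on flow cell 2 10 for sedentary mice. They were 14 at ZT12 without the libraries that stood apart, 20 for the difference with surrogate variables, 10 for sedentary mice with GC offsets, and 9 for exercised mice without the libraries with skeletal muscle transcripts. The cause was not tested.

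Of 136 values of named genes, 136 kept their direction and side of the threshold with DESeq2 size factors, 133 with DESeq2 and 123 with GC offsets. On flow cell 2 alone 80 kept their direction but no longer passed the threshold, as did 38 on flow cell 1 alone. Without the flow cell term it was 41, and with library totals or without the skeletal muscle libraries 27 each. Loss of the threshold does not mean a smaller fold change, and fits with fewer mice have less power. For Per1, time of day in exercised mice, the value (-0.01) turned positive with limma-voom (0.0171), no flow cell term (0.20), flow cell 2 alone (0.52), the compared groups alone (0.0552), surrogate variables (0.56, adjusted p = 0.0203), without the libraries that stood apart (0.0301), with GC offsets (0.35) and with those and the block (0.31). Nr4a1 in the difference (-0.35) turned to 0.0908 on flow cell 2. The cause was not tested. In the shallowest library 0.575 CPM corresponded to 3 counts, so low genes such as Npas2 at ZT12 were at the limit of detection there.

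Replicate numbers might pair mice across groups, but libraries of the same number correlated at a median of 0.00651 (36 pairs, -0.445 to 0.781), others at -0.022, and 10 of 24 fitted best with their own number. At ZT12 alone, sedentary and exercised libraries of the same number correlated at 0.0564 to 0.484, 5 of 6 above 0.1, and at ZT0 at -0.383 to 0.138. With the replicate number as a block 160 genes passed for exercise at ZT0, 31 at ZT12 and 23 at both times. For time of day it was 608 in sedentary and 220 in exercised mice. With GC offsets added 266 passed at ZT0, 502 for sedentary mice and 1 (Per1) for the difference. With the block, camera no longer called the epicardium list for the difference (adjusted p = 0.0549). It then called the lymphocyte (adjusted p = 0.0442) and skeletal muscle lists (adjusted p = 0.0163) for the difference.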

Other observations

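The regroupings counted for single lists were tests chosen after the results were seen. In further gene groups some members differed. Of 23 chaperone genes, 6 were lower at ZT12 than at ZT0 in sedentary mice, with 8 lower and 1 higher when adjusted over the list alone, and the list was not called (median -0.20, adjusted p = 0.199). Of 17 genes of the endoplasmic reticulum and integrated stress response, 5 were lower and 2 higher, with 9 and 2 when adjusted over the list alone, and the list was not called (median -0.38, adjusted p = 0.0547). Both lists were called lower on flow cell 2 (adjusted p = 4.35e-05 for chaperones and 0.00133), with 2 surrogate variables (1.14e-05 each), without the 3 libraries that stood apart (0.00339 and 0.0055) and with GC offsets (0.048 and 0.0338), and not on flow cell 1 (0.705 and 0.446). The folding factors Sdf2l1 (-1.56 ± 0.29, not passing with GC offsets), Creld2 (-1.52 ± 0.27) and Manf (-1.34 ± 0.24) were lower and Herpud1, of protein degradation at that compartment, higher (1.19 ± 0.17). After exercise at ZT0 Chac1 (2.01 ± 0.40) and Herpud1 (0.74 ± 0.17) of this list rose (median 0.18, adjusted p = 0.00823, and 0.201 with an estimated correlation), Herpud1 not with GC offsets. The list was not called on flow cell 1 (median 0.08, adjusted p = 0.138, against 0.22 on flow cell 2) nor without the 6 libraries with skeletal muscle transcripts (adjusted p = 0.259, 0 members past the threshold). The latter fit keeps 3 ZT0-EX libraries, all on flow cell 1. After exercise at ZT12 the list was called higher (median 0.25, adjusted p = 0.0163, and 0.353 with an estimated correlation), with 0 of 17 past the threshold over all genes by edgeR and 1 higher when adjusted over the list alone, and it was not called on flow cell 1 (adjusted p = 0.122). In exercised mice 1 of the 17 was lower at ZT12, with 5 lower and 1 higher when adjusted over the list alone (median -0.28, adjusted p = 0.00348, and 0.183 with an estimated correlation). Of 20 hypoxia and angiogenic genes, 3 were lower and 1 higher in exercised mice at ZT12, with 6 and 2 when adjusted over the list alone (median -0.34, adjusted p = 0.00454, and 0.183 with an estimated correlation). Neither list was called in exercised mice on flow cell 1 (adjusted p = 0.27 each) or without the libraries with skeletal muscle transcripts (adjusted p = 0.171 and 0.0525).

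In the fit to all 24 libraries, 0 of 21 glycolysis genes passed over all genes by edgeR at either time and 2 rose at each when adjusted over the list alone, with list medians of 0.26 at ZT0 (adjusted p = 0.0124, and 0.547 with an estimated correlation) and 0.33 at ZT12 (adjusted p = 0.00124, and 0.639 with an estimated correlation), where it was 0.13 with GC offsets (adjusted p = 0.0359). At ZT12 the glycolysis list was not called on flow cell 2, with 2 surrogate variables or without the 3 libraries that stood apart (adjusted p = 0.107, 0.305 and 0.137), and at ZT0 not on flow cell 1 or with surrogate variables (0.145 and 0.143). With 2 surrogate variables 1 glycolysis gene rose at ZT0 and 2 at ZT12, and without the 3 libraries that stood apart 2 rose at ZT0 and 0 at ZT12. Of 33 nuclear-encoded oxidative phosphorylation genes 0 passed at ZT0 by edgeR, over all genes or over the list alone, where camera called the list lower (median -0.38, adjusted p = 0.00524, and 0.592 with an estimated correlation), but not on flow cell 2 (adjusted p = 0.0724) or with 2 surrogate variables, where its direction turned (adjusted p = 0.5). Of 26 PPAR target and fatty acid genes 0 passed at either time in the fit to all 24 libraries, over all genes or over the list alone. Pdk4 passed at both times with 2 surrogate variables and without the 3 libraries that stood apart, and at ZT0 with GC offsets, and the list was not called (median 0.02, adjusted p = 0.455 at ZT0, and 0.06, adjusted p = 0.782 at ZT12). Atrial markers had a median of 1.42 after exercise at ZT12 (adjusted p = 0.00249, and 0.639 with an estimated correlation, at 2.01 on flow cell 1 and 0.63 on flow cell 2) and 0.93 between ZT12 and ZT0 in exercised mice (adjusted p = 0.000623, and 0.328 with an estimated correlation), with 0 of 10 past the threshold over all genes by edgeR in both comparisons, fitted to all 24 libraries (2 higher in exercised mice with 2 surrogate variables and 3 without the libraries that stood apart).

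In 100 regroupings, the real grouping included, a camera p as small arose for exercise at ZT0 in 1 for the heat shock list, 2 for the immediate early list, 2 for the glucocorticoid-responsive list and 1 for the clock list, against 6 for lymphocyte and 12 for macrophage markers, 11 for cell cycle, 14 for glycolysis, 14 for mitochondrial biogenesis, 21 for ion channels, 24 for interferon-stimulated genes, 26 for the endoplasmic reticulum list, 27 for skeletal muscle and 48 for oxidative phosphorylation. At ZT12 it arose in 1 for the heat shock, 1 for the immediate early and 1 for the glucocorticoid-responsive list, 2 for the endoplasmic reticulum list, 9 for the mitochondrially encoded and 9 for the adipocyte list, 10 for glycolysis and 19 for atrial markers. For time of day in sedentary mice it arose in 1 for the clock, 1 for the cardiac stress, 2 for the matrix, 3 for the glucocorticoid-responsive, 5 for the sterol and 39 for the mitochondrially encoded list. In exercised mice it arose in 1 for the clock, 1 for the cardiac stress and 2 for the matrix list, and in 6 to 31 for the other 11 lists called, the highest being interferon-stimulated genes. These counts were not adjusted for the number of lists.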
